A study of Escherichia coli with 12 samples.

How the data were processed

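Total RNA of Escherichia coli K12GFP-UTL2 was measured on 12 two-colour spotted arrays. Per the labels' protocols, a pre-culture in LB medium with ampicillin was divided between a pair of shaking flasks, nalidixic acid was added to the test flask at 0.25 to 0.3 mg/L, and the other flask served as the reference. RNA was extracted from both, and 150 µg per dye was reverse transcribed with Cy3- or Cy5-labelled dCTP, per the labels. The labels name an oligo(dT) primer, which is unusual for bacterial RNA. At 0, 0.5, 1, 2 and 8 h the treated RNA was hybridised against the reference on 2 arrays with exchanged dyes, and on 2 further arrays treated RNA of 4 h was hybridised against treated RNA of 0.25 h, also with exchanged dyes. For 0.5 to 8 h the treatment field of the labels describes both channels as treated, while the titles and the file headers name a reference channel. The titles and headers were followed.

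The deposited values of each array are spot intensities with the background already subtracted, per the file headers, with a quality code per channel whose meaning is not given in the sources used here. The scanner, the image software and the way the background was estimated are also not given in the sources used here. The intensities had not been normalized between the channels. Each array holds 4608 spots. The deposited value table of the series holds, for each array, the log10 of the treated over the reference signal plus the log10 ratio of the summed signals. This was found by setting each column against the intensities of its array, where the slope lay between 0.999 and 1.00 and the lowest r rounded to 1.00. Its log10 scale, centring and direction are therefore known, and values are missing where a signal was 0 or lower. The design text of the series states that effects of the growth curve were removed computationally, and the deposited values show no step beyond this scaling.

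Of the 4608 spots, 4087 carry 1 gene symbol in the platform annotation, 0 carry several and 521 are not listed there. Symbols were updated through the gene ID with the RefSeq gene table of assembly ASM584v2, which matched 4086 of the 4087 probes and changed 197 symbols. The table was used only for names and gene order, and no coordinates are given because no genome build is named for the arrays. The named spots cover 4038 genes, of which 49 have 2 spots that were averaged. Signals at or below 0 have no logarithm and were left out. The log2 ratio of treated over reference was normalized within each array by a loess curve on intensity with span 0.3 (limma 3.58.1 in R 4.3.3). Normexp background correction had been planned for uncorrected signals and was not applied, because the deposited intensities were already corrected.

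The labels describe 1 pair of flasks, so the dye-swapped arrays of a time are 1 replicate and a single time has no replicate. The SD given for a time is that of its 2 arrays and covers no biological spread between cultures. At 8 h and for 4 h over 0.25 h, whose arrays share columns, it may also hold differences between RNAs of different samples. The main comparison asked whether the mean log2 ratio over 0.5, 1, 2 and 8 h differed from 0, with limma (lmFit, eBayes) on the 4 dye-swap means and Benjamini-Hochberg adjustment over the genes with values for at least 3 of the times. Its p-values measure only the spread between time points of this pair of flasks. A second limma fit tested the slope on log2 time. At each time, genes at least 2-fold different in the same direction on both arrays were counted without a test. Correlations between arrays are across genes, which are not independent replicates.

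The 27 gene lists were fixed before the data were examined, and 863 of 885 list members were matched to a spot. They were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation and with fry, over the lists with at least 5 members measured at every time. At each time a list's median was set against 10000 random lists of the same size matched on mean log2 intensity. The named genes were also fixed by rule before the data were examined. The rule takes the 10 highest and 10 lowest means over 0.5 to 8 h past an adjusted p of 0.05, filled with the largest means among genes of the same sign on all 8 arrays. It further takes, for each time, the 5 highest and 5 lowest among genes at least 2-fold different on both arrays, up to 4 members of each list with the largest absolute mean, and 16 genes chosen for their link to quinolones, SOS response or efflux. Further genes are named as chosen after their values were seen.

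The signal of an array limits its precision. Median signals of the channels ranged from 189 to 9981.5 intensity units, and 1271 of 4608 spots were at or below 0 in the dimmest channel, against 0 to 134 in the channels of other columns. The number of arrays, 2 per time, limits the precision of every value.

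The scripts were tested on simulated arrays built from the real intensities and spreads. For the mean over 0.5 to 8 h among 4038 genes, 0 of 67 genes changed by 1 log2 unit were recovered, 23 of 67 changed by 2 and 51 of 66 changed by 3, with 1 call of an unchanged gene. For the slope, 0 of 100 genes with a simulated slope of 1.5 per doubling of time were recovered, so the test for a trend had little power. Alternatives were other normalizations, filters on dim spots, the deposited log10 value table, other thresholds, arrays in place of time-point means, subtraction of 0 h, single dye orientations and each time left out in turn. Loess per print block, a floor of 100 and an offset of 50 on the signals, and the restriction to genes with all 4 times were added after seeing the data.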

Results

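The response of Escherichia coli K12GFP-UTL2, a K-12 strain carrying GFP by its name, to nalidixic acid was followed over 8 h. Nalidixic acid is a quinolone that inhibits DNA gyrase, the enzyme that introduces negative supercoils into DNA. Treated and untreated cultures came from 1 pre-culture, and each of 0, 0.5, 1, 2 and 8 h was measured on 2 dye-swapped arrays. A further pair of arrays compared treated cells at 4 h with treated cells at 0.25 h. Values are log2 ratios of treated over reference, given as the mean ± SD of the 2 arrays of a time. No time had a biological replicate.

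The arrays differed in how well a dye swap repeated itself. Across genes, the Pearson correlation of the 2 arrays was 0.255 at 0 h, 0.167 at 0.5 h, 0.724 at 1 h and 0.494 at 2 h. It was -0.12 at 8 h and -0.06 for 4 h over 0.25 h. The arrays at 8 h and those of 4 h over 0.25 h also shared channels. The treated channel of the 8 h array with treated RNA in Cy5 held the same signal in all 4608 spots as the 4 h channel of the array with 4 h RNA in Cy3. The reference channel of the other 8 h array had the same quality code in every spot as a 0.25 h channel, with r = 0.994 between them. The counts of genes past the test and the calls of the gene lists are therefore given also without 8 h.

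**Figure D1:**
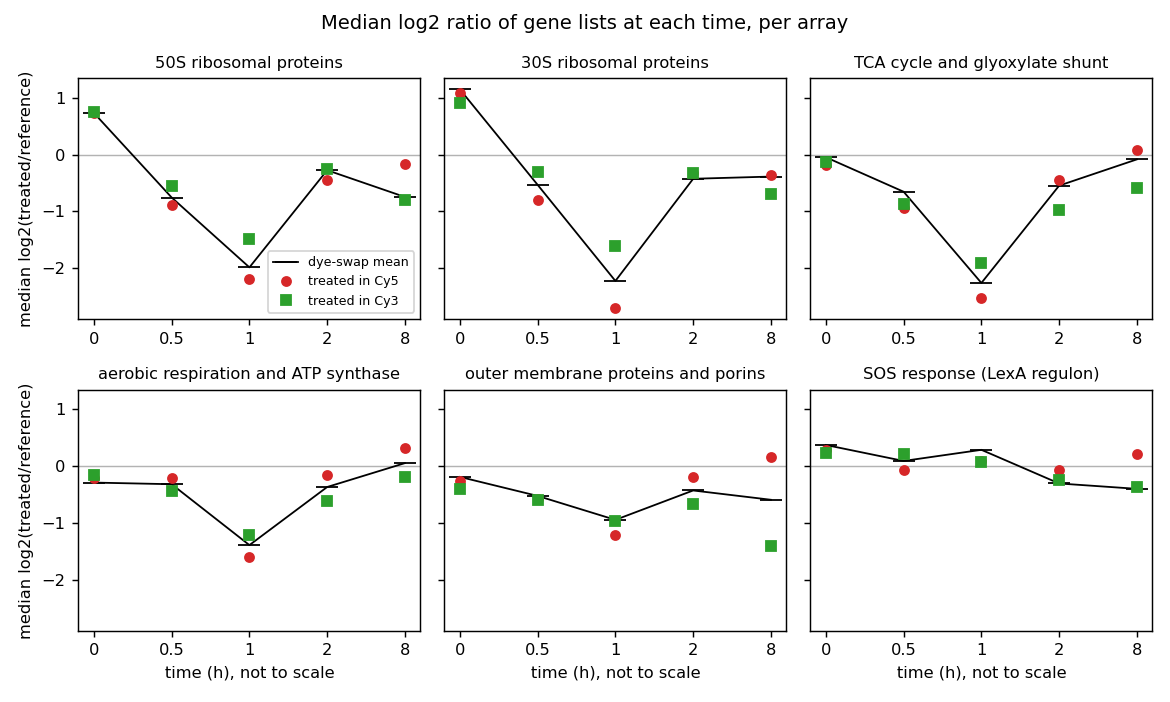
Median log2(treated/reference) of 6 gene lists at 0, 0.5, 1, 2 and 8 h, with time on an unscaled axis. Circles and squares are the arrays with treated RNA in Cy5 and in Cy3, and the line joins the medians of the dye-swap means. The 50S and 30S ribosomal protein genes have medians of 0.73 and 1.15 at 0 h, and of -1.98 and -2.22 at 1 h.

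The first comparison asked which genes differed between treated and reference cells over 0.5 to 8 h. Expression of raiA and fimA was lower in treated cells. For raiA (b2597), which encodes a ribosome-associated inhibitor of translation, the mean log2 ratio was -3.64 ± 0.44 (SE, n = 4 times), a 12.5-fold lower level, with a limma adjusted p of 0.0223. The ratio of raiA was below 0 on 10 of 10 arrays of treated against reference, those at 0 h included. At 0 h it was -5.89 ± 1.93, so the lower level of raiA was present at the first sampling. With 0 h subtracted the mean of raiA was 2.24 (limma adjusted p = 0.0263), with the error of the 0 h arrays missing from that test. For fimA (b4314), the major subunit of type 1 fimbriae, the mean was -3.47 ± 0.46 (SE, n = 3 times; limma adjusted p = 0.0415), with -3.38 at 0.5 h, -3.80 at 1 h and -3.23 at 2 h, and the ratio at 0 h was -1.36 ± 0.40. These were the only 2 of 4019 genes past the limma test, both lower, and 527 genes had an unadjusted p under 0.05. Scale normalization or either dye orientation alone gave 0 genes, and subtraction of 0 h gave 170 (77 higher, 93 lower). Without 8 h, 2 of 3998 genes passed limma's test, with fimA at an adjusted p of 0.048 and acnB at 0.048. The mean of raiA was then -3.62 (limma adjusted p = 0.0716). Without 2 h no gene passed, with raiA at -3.25 (limma adjusted p = 0.0588). The gene fimA was testable only with 0.5, 1 and 2 h all included.

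Other genes had the same sign on all 8 arrays but did not pass the test. Among the lower ones were acnB, which encodes aconitase of the TCA cycle (-2.78 ± 0.45, SE; limma adjusted p = 0.0734), yobF (-2.72 ± 0.44; 0.0734), and mdh, malate dehydrogenase (-2.38 ± 0.42; 0.132). The porin gene ompF had a mean of -2.23 ± 0.45 (limma adjusted p = 0.185), with -3.00 ± 0.47 at 1 h. The ribose-binding protein gene rbsB was at -2.90 ± 0.58, gloB at -2.62 ± 0.50, and the cold shock family genes cspE and cspC at -2.61 ± 0.56 and -2.32 ± 0.63. Among the higher ones were nohA of a prophage (2.30 ± 0.59), the putative proline permease gene proY (2.27 ± 0.57), yajL (2.12 ± 0.53) and wcaK of colanic acid synthesis (2.04 ± 0.41; limma adjusted p = 0.185). These means depend on single times. Without 8 h rbsB was at -2.07, cspE at -1.84 and nohA at 1.71, and without 1 h cspC was at -1.52, proY at 1.58 and yajL at 1.42. In all, 113 genes were above 0 and 93 below 0 on all 8 arrays, of 2931 with values at every time. Independent signs on 8 arrays would give 0.781% of genes in both directions together. The 2 arrays of a time share their RNA and are not independent, so that share cannot serve as a chance level. For the slope on log2 time, 0 of 2931 genes passed the limma test, and 158 had an unadjusted p under 0.05.

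**Figure D2:**
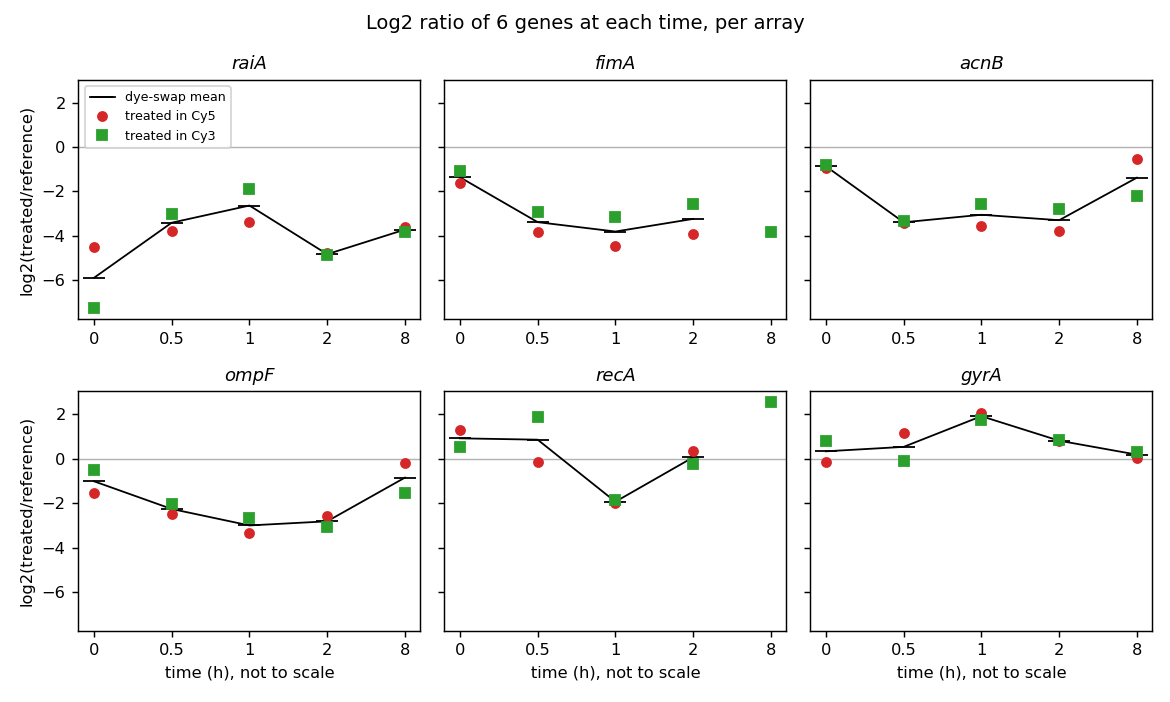
Log2(treated/reference) of 6 genes at 0, 0.5, 1, 2 and 8 h, with time on an unscaled axis. Circles and squares are the arrays with treated RNA in Cy5 and in Cy3, and the line joins their means where both arrays gave a value. Genes raiA, fimA, acnB and ompF lie below 0 on every array drawn, recA has -1.94 at 1 h and gyrA has 1.91.

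The gene lists asked which functions moved together over 0.5 to 8 h. With camera at its preset correlation, 6 of 26 lists were lower in treated cells and 0 were higher. They were 50S ribosomal proteins (median log2 ratio -0.88, 25 genes, adjusted p = 1.4e-06), 30S ribosomal proteins (-0.72, 16 genes, 0.000157), and TCA cycle and glyoxylate shunt (-0.57, 12 genes, 0.000157). The others were outer membrane proteins and porins (-0.87, 14 genes, 0.00172), aerobic respiration and ATP synthase (-0.69, 25 genes, 0.00276), and cold shock proteins (-0.61, 10 genes, 0.0402). None of the 6 passed with an estimated correlation (camera adjusted p = 0.526 with an estimated correlation) or with fry (lowest adjusted p = 0.213). Without 8 h, all 6 passed camera at the preset correlation, and so did translation factors and RNA polymerase (adjusted p = 0.025) and glycolysis (0.0152), while with an estimated correlation the adjusted p was 0.754. Without 1 h, 4 lists passed, and aerobic respiration (adjusted p = 0.214) and cold shock (0.165) did not. The mean log2 ratio then went from -0.83 to -0.53 for 50S ribosomal proteins, from -0.77 to -0.44 for 30S ribosomal proteins and from -0.53 to -0.26 for aerobic respiration.

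Ribosomal protein genes, which follow the growth rate, had medians above 0 at 0 h and below 0 at each later time. At 0 h the medians were 0.73 for the 33 genes of the 50S subunit and 1.15 for the 21 genes of the 30S subunit, each above all 10000 random lists. At 1 h they were -1.98 and -2.22, and 0 of 10000 random lists were as low. Random lists draw genes singly, while the estimated correlation between members was 0.31 for 50S and 0.44 for 30S genes. The random lists therefore overstate how rare such medians are. Of the 33 genes, 23 were at least 2-fold lower on both arrays at 1 h and 0 were higher, and of the 21 genes 15 were lower and 0 higher. The ratio of rplF went from 1.33 ± 0.29 at 0 h to -4.27 ± 1.41 at 1 h, and that of rpsN from 1.73 ± 0.66 to -3.48 ± 0.73. For rplN the values were 1.00 ± 0.04 and -3.48 ± 0.76. At 2 h the medians were -0.28 and -0.43. At 8 h they were -0.75 and -0.39, above 2.03% and 34.7% of random lists, so that of the 30S genes was not unusually low. For 4 h over 0.25 h they were -2.01 and -2.00, but both came mainly from the array with 4 h RNA in Cy3 (-3.08 and -3.90), since the same genes had -0.30 and -0.55 on the other. No member passed limma's test over all genes, and adjusted over the list alone 0 of 33 and 0 of 21 passed. Without 8 h, 6 of the 33 were lower adjusted over the list alone, and 0 of the 21.

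Genes of aerobic energy metabolism, which oxidises carbon sources with oxygen, had their lowest medians at 1 h. Of 20 TCA cycle genes, 11 were at least 2-fold lower on both arrays and 1 was higher, with a median of -2.26 against -0.05 at 0 h. The median at 1 h was nearer 0 over the 11 genes above the median intensity (-1.05) and the 14 with code 0 (-1.70). Adjusted over the list alone, 9 of 20 were lower over 0.5 to 8 h and 1 was higher, while 0 passed over all genes. Without 8 h, 10 were lower and 1 was higher adjusted over the list alone. The ratios at 1 h were -3.05 ± 0.70 for acnB, -3.10 ± 0.73 for sdhC, a succinate dehydrogenase subunit, -2.94 ± 0.93 for mdh and -2.83 ± 0.77 for sucD. Of 30 genes of aerobic respiration and ATP synthase, 16 were lower and 1 was higher at 1 h, with a median of -1.39 against -0.29 at 0 h. Adjusted over the list alone 1 was lower, or 3 without 8 h. The ATP synthase gene atpF was at -1.88 ± 0.15 and the NADH dehydrogenase gene nuoC at -2.60 ± 1.24, whereas nuoG of the same complex was at 3.66 ± 0.51. Glycolytic genes had a median of -1.22 at 1 h, with 8 of 21 lower and 0 higher, among them gapA (-3.48 ± 1.23) and fbaA (-3.51 ± 1.23). At 0 h their median was already -0.45, above 0.24% of random lists. Adjusted over that list alone, 3 were lower, or 1 without 8 h.

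Of 19 genes of outer membrane proteins, 9 were at least 2-fold lower at 1 h and 1 was higher, and adjusted over the list alone 2 of 19 were lower over 0.5 to 8 h and 6 were lower without 8 h. The ratios of ompF at 0.5, 1 and 2 h were -2.26 ± 0.34, -3.00 ± 0.47 and -2.82 ± 0.35, and those of ompA were -2.09 ± 0.03, -3.08 ± 0.77 and -3.44 ± 0.54. For ompC they were -1.18 ± 0.07, -3.29 ± 0.56 and -0.89 ± 0.31. In the cold shock list, 5 of 12 genes were lower at 1 h and 0 were higher, and 2 were lower adjusted over the list alone, or 1 without 8 h. The median at 1 h was -0.87, above 3.87% of random lists.

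The SOS response, the LexA-controlled response to DNA damage, did not pass the test as a list (camera adjusted p = 0.662, 22 genes, and 0.993 without 8 h; 0 of 31 members adjusted over the list alone). Its medians were 0.37 at 0 h, 0.09 at 0.5 h, 0.29 at 1 h and -0.30 at 2 h. The median at 0 h was above 99.8% of random lists, and those at 0.5, 1 and 2 h above 70.6%, 84.1% and 7.72%. At 1 h, 9 members were at least 2-fold higher and 5 lower. Ratios at 1 h were 2.44 ± 0.62 for the endonuclease gene cho and 1.74 ± 0.28 for yafO, against -1.94 ± 0.11 for the recombinase gene recA, -1.59 ± 0.27 for recN and -7.87 ± 4.14 for sbmC, which encodes an inhibitor of gyrase. For lexA it was 0.29 ± 0.59, for the division inhibitor sulA -0.25 ± 0.12, and for umuD -2.30 ± 2.59.

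Nalidixic acid acts on gyrase. The subunit genes gyrA and gyrB had ratios of 1.91 ± 0.21 and 1.14 ± 0.50 at 1 h and of 0.81 ± 0.04 and 0.74 ± 0.04 at 2 h, with 0.33 ± 0.66 and -0.49 ± 0.52 at 0 h. Over 0.5 to 8 h the means were 0.86 ± 0.42 for gyrA (SE, n = 4 times; limma adjusted p = 0.408) and 0.76 ± 0.46 for gyrB (SE, n = 3 times; limma adjusted p = 0.493), which did not pass, nor did they without 8 h (0.421 and 0.483). At 1 h the gene of topoisomerase I, topA, was at -1.15 ± 0.72, and the topoisomerase IV genes parC and parE were at -0.37 ± 0.13 and -0.60 ± 0.22. The nucleoid protein genes hupB and hns were at -3.50 ± 1.00 and -1.47 ± 0.10. The whole list of topoisomerases and nucleoid proteins did not pass camera (adjusted p = 0.0946, and 0.260 without 8 h). Among genes of drug efflux, acrA was at 1.28 ± 1.18, emrA at 1.11 ± 1.84 and marA at -0.65 ± 0.71 at 1 h, and the list did not pass (adjusted p = 0.964, and 0.993 without 8 h). The stationary-phase sigma factor gene rpoS was at -3.46 ± 0.52 and the division gene ftsZ at -2.51 ± 0.69.

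The remaining lists did not pass camera over 0.5 to 8 h. Adjusted p was 0.126 for translation factors and RNA polymerase, 0.104 for glycolysis, 0.199 for DNA repair outside the LexA regulon, and 0.479 for DNA replication, heat shock, envelope stress and aminoacyl-tRNA synthetases. It was 0.369 for purine and pyrimidine synthesis, 0.409 for amino acid synthesis, iron uptake, toxin-antitoxin and prophage genes and for tryptophanase and LB catabolism, and 0.662 for the RpoS response. It was 0.712 for flagella and chemotaxis, 0.807 for oxidative stress and for anaerobic respiration, and 0.963 for cell division. Cell division had a median of 0.05 but a mean of -0.02, and efflux a median of -0.14 in a test whose direction was upward. Glutamate-dependent acid resistance had too few genes measured at 8 h and had an adjusted p of 0.272 without it. Adjusted over its own list alone, 2 of its genes were lower, but 0 without 8 h. In the same way 1 gene of LB catabolism was lower with and without 8 h, and 1 gene of anaerobic respiration only without 8 h. Apart from translation factors and glycolysis, the lists of this paragraph had an adjusted p of 0.138 to 0.993 without 8 h.

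The comparisons at single times asked how many genes differed as the exposure lengthened. At 1 h, 625 genes were at least 2-fold higher and 629 lower on both arrays, of 4023. Independent arrays would give 452 in all. The highest were ycfH (4.65 ± 0.53), afuC (4.48 ± 0.41), mhpF (4.35 ± 0.88), proY (4.35 ± 0.26) and the copper efflux gene cusA (4.29 ± 0.30). The lowest were sbmC, ymfD (-5.54 ± 0.22), the formate channel gene focA (-4.81 ± 1.78), yqhD (-4.80 ± 1.83) and cspC (-4.75 ± 3.31). At 0 h, the first sampling, 120 genes were higher and 88 lower, of 3927, led by fbaB (2.65 ± 0.76) and lacZ (2.64 ± 1.64) and by raiA and btsT (-3.34 ± 1.32). Independent arrays would give 72.1 in all.

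At 0.5 h, 35 genes were higher and 108 lower, of 4028, with 45.2 given by independent arrays. Both directions together were 3.55% of genes, below the 5.30% at 0 h, so the count did not rise over that of the first sampling. The highest were yfgH (4.63 ± 4.78), gadE, an activator of acid resistance (3.09 ± 1.04), ydjG (2.93 ± 2.69), fryB (2.75 ± 1.38) and rhtA (2.08 ± 1.46), and the lowest were hdeA, a periplasmic acid chaperone (-4.42 ± 1.84), raiA, acnB, fimA and dapD (-3.10 ± 0.37). At 2 h, 143 were higher and 356 lower, of 4022, with 181 given by independent arrays. Among the 2014 genes above the median intensity, 117 were higher and 130 lower, so the split towards lower was mostly absent there. The ratio of raiA at 2 h was -4.82 ± 0.07, that of potE -3.87 ± 1.15 and that of nrdR -3.62 ± 1.89. The highest were yhaH (4.45 ± 4.68), uvrD (3.54 ± 2.90), sapC (3.20 ± 2.92), glnS (3.11 ± 2.77) and proY (2.79 ± 1.49).

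At 8 h, 235 genes were higher and 208 lower, of 2952, fewer than the 529 that independent arrays would give, and 630 genes were 2-fold different in opposite directions. The lowest included rbsB (-5.39 ± 2.84), frlB (-5.21 ± 2.12), cspE (-4.92 ± 0.80) and the RNA polymerase gene rpoC (-4.67 ± 1.82), and the highest included caiT (5.68 ± 4.07) and elfD (5.14 ± 1.16). Within the treated culture, 232 genes were higher and 238 lower at 4 h than at 0.25 h, of 2901, with 456 given by independent arrays. A further 479 genes were 2-fold different in opposite directions. The genes higher on both arrays were led by yecE (5.32 ± 1.99) and kdpB (5.24 ± 3.83), and the lower ones by mioC (-4.53 ± 0.39) and yegH (-4.43 ± 3.18). This comparison includes growth as well as exposure. The dye-swap means at 8 h and of 4 h over 0.25 h correlated across genes with r = 0.565, and these arrays share channels. The ratios and SDs of genes named for these arrays may therefore mix RNAs of different samples.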

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

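All tests of explanations in this part were chosen after the results were seen. Differences between times were not tested, since each time has 1 pair of flasks. They are listed where both arrays of a time lay on the opposite side of 0 from both arrays of another time, over 0 to 2 h, and the times differed by at least 1 log2 unit. The largest such difference is given for each item.

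The log2 ratio of treated over reference at 1 h minus that at 0 h was -3.37 for the median of 30S ribosomal proteins, -2.72 for 50S ribosomal proteins and -1.11 for translation factors and RNA polymerase. Among single genes it was -3.99 for rpoS, -2.85 for recA, -2.85 for umuD and -2.13 for recN, and 4.18 for eutE, 4.12 for yfdC, 3.36 for yfcR and 1.63 for gyrB. The ratio at 2 h minus that at 0 h was -1.42 for sulA and -1.01 for lexA. The ratio at 2 h minus that at 1 h was 1.04 for parC and 1.16 for the median of topoisomerases and nucleoid proteins. Spots with no gene listed for them were also examined. At least 2-fold different on both arrays were 35 of 482 such spots at 0 h, 19 of 519 at 0.5 h, 94 of 515 at 1 h, 114 of 518 at 2 h and 45 of 303 at 8 h. At 1 h this was 18.3% against 31.9% of spots with a gene, and at 2 h 22.0% against 12.7%, where 101 of the 114 were lower. The spots without a gene were dimmer, with a median log2 intensity of 11.19 against 11.56. Among named genes the split towards lower at 2 h was mostly absent above the median intensity. Whether dimness accounts for the share at 2 h was not tested.

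The first pattern weighed is the lower level of 4 lists at 1 h, the 50S and 30S ribosomal proteins, the TCA cycle and aerobic respiration. A loss of ratio at bright spots could not be decided. Of 10000 random lists matched on intensity, 0% had a median as low as any of the 4. The loess curve had already removed the trend of ratio with intensity, so that matched lists lay near 0 beforehand, and the 4 lists were taken up for their low medians. The choice among the normalizations tried is argued against. Over all settings the median nearest 0 was -1.05, that of the 11 TCA cycle genes above the median intensity. Over the other normalizations it was -1.12, that of aerobic respiration with scale normalization. Each of these settings centred the ratios of an array near 0, so a shift of all genes together stays open. A constant difference between the flasks would show at 0 h, where the lowest of the 4 medians was -0.29 and the highest was 1.15. The lowest, of aerobic respiration, was above 1.71% of random lists and near its medians at 0.5 h (-0.32) and 2 h (-0.37). A constant difference thus stays open for that list at those times, while its median at 1 h was -1.39. A difference in growth between the flasks after division, with or without an action of the drug, stays open and cannot be separated with 1 pair of flasks.

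The second pattern is the sharing of channels between the 8 h arrays and those of 4 h over 0.25 h. A repeated hybridisation of 1 RNA is argued against for the column found under both 8 h and 4 h, since 100% of its signals were identical, and the highest share in any pair of columns with differing codes was 0.109%. That column is labelled as Cy5 signal of 8 h on 1 array and as Cy3 signal of 4 h on the other. The same signals cannot be both, so at least 1 of these assignments is wrong. For the other shared column, which is not identical, a column deposited under the wrong sample is a candidate explanation. On these arrays an RNA correlated with itself across the dye swap with a Spearman rho of at most 0.505, against at least 0.666 at 0 to 2 h. The 8 h reference and the 0.25 h RNA, which do not involve the dim column found at both times, had 0.393 and 0.388. Each of these values does involve the other shared column, so they are no separate check. The unshared columns at 8 h are the reference of the array with treated RNA in Cy5 and the treated RNA of the other array. They had a Spearman rho of 0.689 with each other, where the same comparison gave 0.434 to 0.850 at 0 to 2 h. Which of the arrays the shared columns belong to stays open.

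The third pattern is the low ratio of raiA at every time, 0 h included. A dye bias of the spot is argued against, since the ratio was below 0 on 10 of 10 arrays in both orientations. A spot near background in both channels is argued against, since its mean intensity over both channels was above that of 66.3% of genes. The treated channel alone was not examined, so a treated signal near background stays open. A difference between the flasks that preceded the drug stays open, since with 0 h subtracted the mean of raiA was 2.24.

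The 4 time points allow 8 sign patterns, so that no share under 0.05 can be reached. In the count of sign patterns with as many calls, 1 of 8 reached the 2 genes found, and the highest other pattern gave 0. For lists, 1 of 8 reached the 6 found, and the highest other gave 5.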

How the results depend on the processing

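Loess per print block, the floor of 100, the offset of 50 and the restriction to all 4 times were chosen after seeing the data, and the other settings before. The 2 genes past the test over 0.5 to 8 h were 1 with median centring, the deposited value table, eBayes with trend and robust, or only genes with all 4 times. They were 0 with scale normalization or with either dye orientation alone, and 4 with spots of code 0 only or an adjusted p under 0.1. With arrays as samples they were 13 (5 higher, 8 lower), on the spread between dye-swapped arrays only, those at 8 h included. With 0 h subtracted there were 170 (77 higher, 93 lower), and raiA reversed to 2.24 (limma adjusted p = 0.0263). The error of the 0 h arrays is then common to all times and missing from the test. Leaving out a time gave 0 to 2 genes (0 without 2 h, 1 without 0.5 h or 1 h). The test for a trend gave 0 genes except 9 without 0.5 h and 1 without 8 h, a range of 0 to 9. The 6 lists became 0 with an estimated correlation, with fry, and with spots of code 0 only, where 11 lists were tested. Leaving out a time gave 4 (without 1 h) to 8 lists (without 8 h). Counts of genes at least 2-fold different moved as follows, with causes not tested. Median centring gave 319 at 0 h and 698 at 8 h. The deposited values, which were also centred on the median of each array and so nearly repeat that setting, gave 313 and 691. Scale normalization gave 566 at 0 h, 474 at 0.5 h, 168 at 8 h and 240 for 4 h over 0.25 h. Genes above the median intensity gave 133, 91, 785, 247, 255 and 250 at 0, 0.5, 1, 2 and 8 h and 4 h over 0.25 h, from fewer genes. Code 0 gave 128 at 0 h, 132 at 8 h and 111 for 4 h over 0.25 h. A 1.5-fold threshold gave 654, 487, 1912, 1155, 730 and 774 in the same order. The dye-swap mean alone gave 457 at 0 h, 410 at 0.5 h, 1022 at 2 h, 1275 at 8 h and 1296 for 4 h over 0.25 h. Limma over 12 arrays counted genes at an adjusted p under 0.05 in place of a fold threshold, among 2792 genes. It gave 0 genes at 0, 0.5 and 2 h and for 4 h over 0.25 h, 94 at 1 h and 5 at 8 h. Its error was the spread between dye-swapped arrays, pooled over all times. The median SD of a pair was 1.35 at 8 h and 1.19 for 4 h over 0.25 h, against 0.37 to 0.42 at 0 to 2 h. The counts of that fit at 0 to 2 h therefore say little about those arrays alone. At 0.5 h the split of 35 higher to 108 lower was 54 to 99 with median centring, 50 to 95 with the value table and 196 to 278 with scaling. At 8 h the split of 235 to 208 was 88 to 44 with code 0 and 105 to 150 above the median intensity, and for 4 h over 0.25 h the latter gave 86 to 164 in place of 232 to 238. At 2 h it gave 117 to 130 in place of 143 to 356. Correlations of dye-swapped arrays at 0, 0.5 and 1 h were 0.142, 0.107 and 0.635 with median centring, 0.142, 0.108 and 0.635 with the value table, and 0.361, 0.343 and 0.756 with print blocks. At 8 h and 4 h over 0.25 h they were -0.014 and -0.10 with median centring, -0.0098 and -0.10 with the value table, and reversed to 0.122 and 0.0367 with print blocks. At 0, 0.5, 1 and 2 h they were 0.521, 0.437, 0.841 and 0.573 among genes above the median intensity, with -0.11 for 4 h over 0.25 h, and 0.552, 0.310, 0.834 and 0.559 with code 0, with -0.17 at 8 h. A floor gave 0.292 at 0 h. The median of 50S ribosomal proteins for 4 h over 0.25 h was -2.01 over the 25 genes of both arrays and reversed to 0.31 over the 33 genes of the array with 4 h RNA in Cy5. Plain subtraction or no background correction could not be run on corrected signals, and a median of spots equals the mean with at most 2 spots.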

Other observations

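All tests in this part were chosen after the results were seen, and the genes it names were chosen after their values were seen. Flagellar genes split at 1 h, with 16 of 51 at least 2-fold lower on both arrays and 10 higher. The regulator genes flhD and fliA were at -3.33 ± 0.70 and -3.50 ± 0.58, the filament gene fliC at -2.48 ± 0.57 and the motor gene motA at -4.50 ± 0.80, whereas flgF was at 2.84 ± 1.14 and cheY at 2.16 ± 0.47. Of 88 genes of amino acid synthesis, 20 were higher and 11 lower at 1 h. For the synthesis of isoleucine and valine, ilvH was at 2.69 ± 0.05 and ilvI, which encodes the other subunit of the same enzyme, at -2.74 ± 1.96. For histidine synthesis hisD was at 3.28 ± 1.07 and hisG, the first gene of the same operon, at -3.29 ± 0.03. Of 38 genes of iron uptake, 10 were higher and 5 lower, with the siderophore receptor genes fepA and cirA at 3.01 ± 2.14 and 2.41 ± 0.06 and the ferrous iron gene feoA at -2.46 ± 0.23. None of these lists passed camera over 0.5 to 8 h.

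If the ratios follow transcription units, genes next to each other on the chromosome should share them. The correlation between neighbours was 0.125 at 0 h, 0.166 at 0.5 h, 0.22 at 1 h and 0.0461 at 2 h, the last being the lowest. In a permutation test with 1000 permutations the adjusted p was 0.0012 at 0 to 1 h, where the unadjusted p was the smallest that 1000 permutations can give, and 0.00799 at 2 h, where the highest permuted value was 0.0638. The correlation was also 0.0754 at 8 h and 0.102 for 4 h over 0.25 h (adjusted p = 0.0012 in both), although the dye-swapped arrays there correlated at -0.12 and -0.06. It therefore does not show that ratios repeated between arrays, and whether the ratios follow transcription units stays open.

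Fewer replication forks in treated cells may lower the ratios of genes near the origin of replication. At 1 h the Spearman rho of ratio with distance in genes from mnmG, which lies next to the origin, was -0.15, which puts the higher ratios near the origin. It was 0.0767 at 0.5 h, -0.015 at 2 h, 0.139 at 8 h and 0.118 for 4 h over 0.25 h, but also 0.179 at 0 h, so the direction was not the same at all times. In a permutation test by circular shifts of the gene order the adjusted p was 0.348 over 6 comparisons, so no relation with distance was found beyond that of shifted orders.

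Inhibition of gyrase may raise the transcripts of gyrase. The ratio of gyrA was above 0 on 5 of 6 arrays at 0.5 to 2 h, with a mean of 1.08 and a limma adjusted p of 0.421, which leaves this open.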
